A study of Arabidopsis thaliana with 9 samples.

How the data were processed

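RNA sequencing was measured in 9 Arabidopsis thaliana libraries in 3 groups of 3: wild type (Col-0) seedlings, ntrc mutant seedlings and young rosette leaves of adult ntrc plants. Per the labels, seedlings were 6 days old, grown on MS medium (a mineral salt medium) in continuous light, and adult plants were 8 weeks old, grown in soil in short days, both at 125 µE per square metre and second. The labels describe the 3 libraries of a group as biological replicates, and each adult library as pooled leaves of several plants. Per the labels' protocols, adult libraries came from a stranded total RNA kit with ribosomal RNA depletion and seedling libraries from a stranded mRNA kit, although the molecule is labelled polyA RNA for both. Adult wild type libraries are not analysed here.

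The authors deposited 1 table of 32833 gene loci by 9 libraries on a log2 scale, and each column is named as its sample. The values are read as log2(FPKM + 1), where FPKM is the number of fragments relative to transcript length and to the mapped fragments of the library. The authors' name for the deposited data gives the unit as FPKM. The rest of this reading rests on the values, which start at 0 and add up to between 602924 and 727692 per library once the logarithm is undone. The log base and the pseudocount are not stated in the sources used here. The submitters' processing notes name FastQC, HISAT2, StringTie and the genome build TAIR10, without versions or settings. The upper quartile of the deposited log2 values was 3.70 in each of the 6 seedling libraries and 2.44 in each of the 3 adult libraries, so the values had been scaled, and separately for the 2 stages. Sequencing depth is unknown, since the table holds no counts, so no interval from counting error is given and precision rests on the spread of 3 libraries. Whether reads were counted by strand is not given in the sources used here.

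Loci were matched by identifier to gene names of the TAIR10.1 RefSeq annotation, which gave a name row for 32548 of 32833 loci. The 285 unmatched loci are the plastid and mitochondrial ones, and no coordinates were taken from that annotation. No 2 libraries held identical values, and 5203 loci were listed at 0 in all 9.

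Seedling genotypes were compared with limma 3.58.1 in R 4.3.3 (linear models with a mean trend and robust moderation), two-sided, on the deposited log2 values with no further scaling. The test covered 18818 genes with at least 1 FPKM in at least 3 of the 6 seedling libraries, and genes passed at a Benjamini-Hochberg adjusted p below 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. The design had assumed FPKM and a pseudocount of 1, and the deposited values were already on that scale. On simulated data over 18818 genes with 200 changed genes, this comparison without a block recovered 18% of the genes changed by 0.5 on the log2 scale, 82% of those changed by 1, 86% of those changed by 2 and 100% of those changed by 3, with 5 false calls among 148. With the block it recovered 20%, 62%, 84% and 96%, with 0 false calls among 131. The simulated noise was drawn independently for each gene, whereas genes of the real libraries vary together. The 200 planted changes also set the adjusted threshold. These shares therefore do not say how many changes of such sizes the real fit would find.

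Whether replicate numbers pair the seedling libraries was checked before the fits were compared. Deviations of genes from their group means correlated between the wild type and ntrc libraries of one number with coefficients of 0.506 for number 1, 0.406 for number 2 and 0.278 for number 3, while different numbers gave -0.388 to 0.115. The libraries were therefore taken as paired by number, a pairing that comes from the values and not from the labels. Because deviations were taken from group means of 3 libraries, positive coefficients for equal numbers push the others towards negative values. That contrast is thus partly built in, and few other ways to match the libraries exist. The pairing was also read from the same values that the blocked fit then tests. The fit fixed before the data were examined has no block, and the fit with the replicate number as a block stands beside each result whose call it changes.

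Before the data were examined, 22 gene lists with 387 members were fixed: iron deficiency regulators, iron acquisition, iron transport, iron storage, plastid iron-sulfur assembly, copper and zinc, chlorophyll synthesis, light-harvesting antenna, photosystems and electron transport, Calvin-Benson cycle, thioredoxins and peroxiredoxins, antioxidant enzymes, flavonoids, salicylic acid defence, auxin, starch, circadian clock, senescence, root, stomatal and dividing-cell markers, and seed reserves. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list moves one way on balance. Benjamini-Hochberg adjustment ran over the 22 lists. Each list's mean per library was also compared by an exact permutation test, for which 3 libraries against 3 cannot go below 0.1. Of the 387 members, 279 had the annotation's symbol, 58 a listed synonym and 17 no symbol in the annotation. The other 33 had a symbol read by hand as another alias of the gene, and they were kept although the rule as first written would have dropped them.

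The rule for named genes, also fixed before, was NTRC, then the 10 largest rises and 10 largest falls past the threshold with separate groups, 16 iron genes as values, called members of the iron lists, and from each other list up to 4 called members or the member with the smallest p. From the blocked fit, the 10 largest rises and falls past the threshold, whether or not their groups were separate, and the called members of the lists were also named, a choice made after the data were seen, and S8H, MYB72, CYP82C4, F6'H1, ZIP3 and IRT3 were also chosen after their values were seen.

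A test of adult leaves against seedlings of ntrc had been planned and was not run, because the stages were scaled separately and differ in tissue, light, medium and kit. Levels of the 2 stages are set side by side as percentile ranks within each library among 32548 nuclear genes, without a test. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile normalization, median ratio scaling, removal of organelle genes, plain moderation, a fit with all 9 libraries, a size threshold of 1, the replicate block, and leaving out each library in turn. Blocked fits with another scaling, without each pair, and with other list tests were added after the data were seen. The block leaves few residual degrees of freedom, and leaving out a pair leaves still fewer. The p-values of such fits therefore lean more on variance pooled over genes than those without a block, and calls gained or lost there are uncertain.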

Results

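NTRC is a chloroplast enzyme that joins an NADPH-dependent thioredoxin reductase and a thioredoxin in 1 protein, and the series asks how its loss bears on iron homeostasis in seedlings and in adult plants. Expression was available as log2(FPKM + 1) for 3 wild type seedling libraries, 3 ntrc seedling libraries and 3 libraries of adult ntrc leaves. Sequencing depth was unknown. Between 18539 and 18829 loci per seedling library and between 15331 and 15460 per adult library reached 1 FPKM. Rank correlations across all genes were 0.973 to 0.983 within groups and 0.972 to 0.981 between seedling libraries of different genotype, ranges that overlap.

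The targeted gene was low in each ntrc library. NTRC (AT2G41680) stood at 149 ± 23.3 FPKM in wild type seedlings, 17.8 ± 1.64 in ntrc seedlings and 15.8 ± 0.616 in adult ntrc leaves (mean ± SD, n = 3 each), the last on its own scale. In seedlings it fell by 2.98 on the log2 scale (SE 0.13), which is 7.91-fold lower, in 3 of 3 pairs, with an adjusted p of 0.000588 (limma, Benjamini-Hochberg). The 3 ntrc seedling libraries all lay below the 3 wild type ones.

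The first comparison asked what the mutation changed in 6-day-old seedlings. Without a block, 1 gene rose and 4 fell among 18818 tested. AT1G75945 rose: it was listed at 0 in 2 wild type libraries and at 0.42 in the third, against 3.36, 3.66 and 3.86 in ntrc (log2 fold change 3.48, SE 0.18, adjusted p = 0.000883, limma with Benjamini-Hochberg). Besides NTRC, the genes that fell were the non-coding locus AT4G04223 (-2.08, SE 0.19), NTMC2T6.2 (AT3G14590, a C2 domain protein; -1.80, SE 0.15) and ARP9 (AT5G43500, an actin-related protein; -1.18, SE 0.093), with adjusted p of 0.0427, 0.0147 and 0.0147 from limma with Benjamini-Hochberg, each in 3 of 3 pairs. At an unadjusted p below 0.05 (limma) there were 943 genes, about as many as that cut-off gives by chance among 18818. The groups were separate for 1837 genes, or 9.76% where chance gives 10%. With the replicate number as a block, 30 genes rose and 43 fell, all 5 genes above among them, and 2185 genes had an unadjusted p below 0.05.

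Leaving out 1 library ended several of these calls while the fold changes moved little, from -2.26 to -1.86 for AT4G04223, -1.88 to -1.73 for NTMC2T6.2 and -1.23 to -1.12 for ARP9. AT4G04223 missed the threshold without any 1 of the wild type libraries or without ntrc library 1 (adjusted p up to 0.339 over the fits that leave out 1 library), NTMC2T6.2 without ntrc library 2 or 3 (up to 0.0946) and ARP9 without any 1 of the wild type libraries or without ntrc library 2 (up to 0.166; limma, Benjamini-Hochberg), and in the blocked fit without pair 1 (0.0538). AT1G75945 was not tested without an ntrc library, nor NTMC2T6.2 without a wild type library, because fewer than 3 libraries then reached 1 FPKM. NTRC passed in each of these fits. The count of falls was 1 without any 1 of the wild type libraries, and that of rises 0 without ntrc library 2 or 3 and 2 without wild type library 1 or ntrc library 1. With a pseudocount of 0.1 the adjusted p was 0.0845 for AT1G75945, 0.0862 for AT4G04223 and 0.0590 for NTMC2T6.2, and with median ratio scaling 0.0588 for AT4G04223 (limma, Benjamini-Hochberg).

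Genes of iron storage were higher in ntrc seedlings. All 7 tested members, ferritins that store iron and relatives of the vacuolar iron transporter, were higher in each of 3 pairs. Their median log2 fold change was 0.75. FER1 (AT5G01600) read 6.89 ± 0.56 in wild type and 8.04 ± 0.52 in ntrc, a difference of 1.15 (SE 0.36), and FER4 (AT2G40300) 4.19 ± 0.28 and 5.11 ± 0.34 (mean ± SD of log2 values, n = 3). Without a block no member passed over all genes (adjusted p = 0.948 for FER1, FER3 and FER4, limma with Benjamini-Hochberg), and 6 of 7 passed when adjusted over the list alone. With the block 4 members rose, FER1 (adjusted p = 0.00987), FER4 (0.0268), VTL2 (log2 fold change 1.13; 0.0370) and VTL1 (0.75; 0.0469), and 7 of 7 passed when adjusted over the list alone (limma, Benjamini-Hochberg). In 5 blocked fits added after the data were seen, with either other scaling or without 1 pair, FER1 kept its call (adjusted p up to 0.0442). VTL1 missed the threshold in all 5 (0.0501 to 0.185), FER4 without pair 1 (0.0649) or 2 (0.0639) and VTL2 without pair 2 (0.123) or 3 (0.0850; limma, Benjamini-Hochberg). FER3 (AT3G56090) had a log2 fold change of 0.60 and an adjusted p of 0.0999 in the blocked fit with all pairs. The list passed limma's camera at the preset correlation (Benjamini-Hochberg adjusted p = 1.31e-07), and had adjusted p = 0.593 with an estimated correlation. The estimate was 0.77, against the preset of 0.01, which treats members that vary together as nearly independent. The storage list's mean per library was separate between the genotypes, at 4.01 ± 0.35 against 4.78 ± 0.34. An exact two-sided permutation test gave p = 0.1, the smallest it allows here, and 0.926 after Benjamini-Hochberg adjustment over the 22 lists. By the same test the unadjusted p was 0.2 for regulators and acquisition, 0.3 for iron transport and light harvesting, and 0.4 for flavonoids. None of these other lists was separate between the genotypes.

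**Figure D1:**
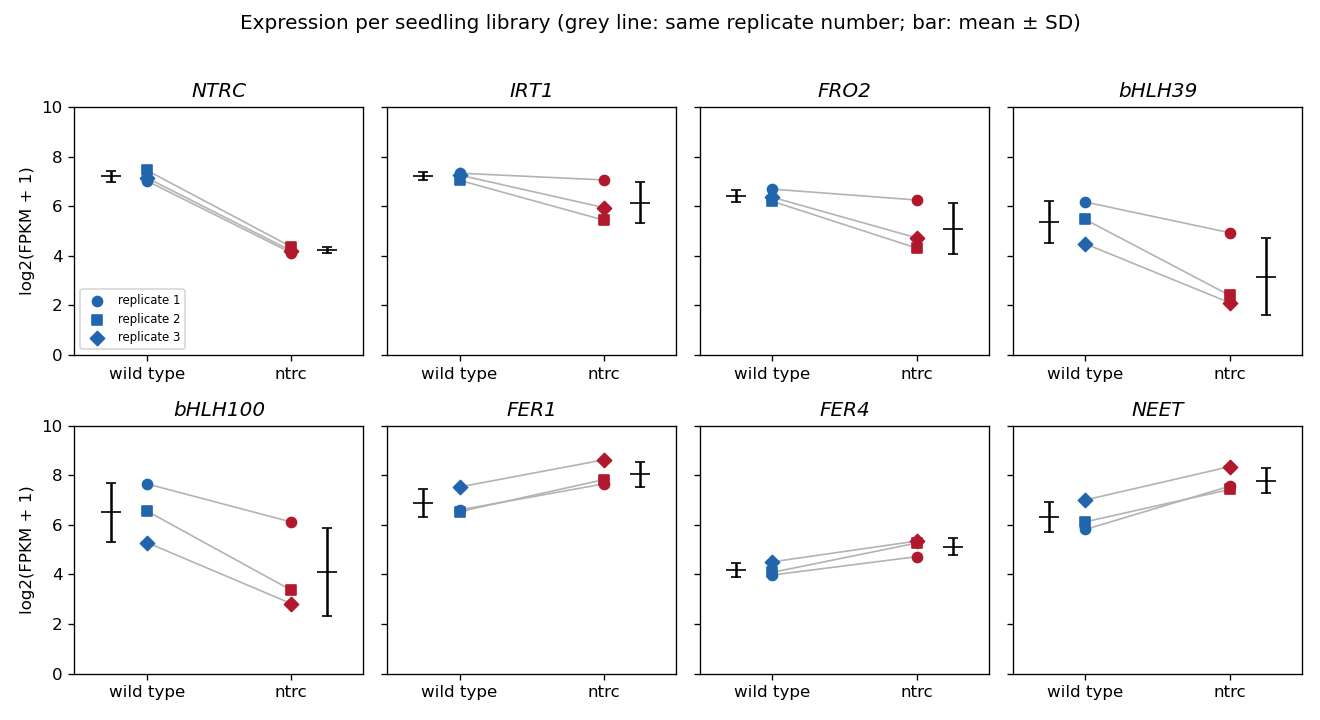
Each panel plots 1 gene's log2(FPKM + 1) in the 3 wild type (blue) and 3 ntrc (red) seedling libraries, with grey lines between libraries of one replicate number and black bars for mean ± SD. NTRC fell from a mean of 7.21 to 4.23, FER1, FER4 and NEET were higher in ntrc in 3 of 3 pairs, and IRT1, FRO2, bHLH39 and bHLH100 were lower in 3 of 3 pairs, with ntrc library 1 the highest of the ntrc libraries.

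Regulators of the iron deficiency response lay lower in ntrc seedlings, by amounts that varied widely between libraries. Of 19 tested members 15 had a negative fold change, 14 of them in each of 3 pairs, and the median was -0.96. The transcription factors of the bHLH subgroup Ib, which work with FIT, had the log2 fold changes -2.50 for bHLH38 (AT3G56970, SE 1.04), -2.23 for bHLH39 (AT3G56980, SE 0.86), -2.40 for bHLH100 (AT2G41240, SE 1.03) and -1.65 for bHLH101 (AT5G04150, SE 0.79). FIT itself (AT2G28160), the main regulator of root iron uptake, had -0.96 (SE 0.39). The small peptides IMA1 (AT1G47400), IMA2 (AT1G47395) and IMA3 (AT2G30766), which promote iron uptake, had -1.90, -2.25 and -1.78, and MYB72 (AT1G56160) had -2.23. PYE (AT3G47640) and BTS (AT3G18290), which act in the same response, had -0.60 and -1.02. A further 3 members lay between -0.78 and -0.45, and the other 5, bHLH factors that include subgroup IVc, between -0.017 and 0.11. None of the 19 passed over all genes, without a block (smallest adjusted p 0.948) or with it (0.0762 for PYE; limma, Benjamini-Hochberg). Blocked fits without 1 pair, added after the data were seen, called other members each time. Without pair 1, 6 regulators fell, among them bHLH38 (-3.10, adjusted p = 0.0149), FIT (-1.36, 0.0326) and IMA2 (-2.60, 0.0326), without pair 2 bHLH101 (-1.29, 0.0240) and IMA1 (-1.41, 0.0159), and without pair 3 BTS (-1.23, 0.0267; limma, Benjamini-Hochberg). Adjusted over the list alone, 0 passed without a block and 13 with it. Camera gave a Benjamini-Hochberg adjusted p of 1.49e-07 at the preset correlation, and adjusted p = 0.593 with an estimated correlation. Pairs such as bHLH38 and bHLH39 or IMA1 and IMA2 are similar in sequence, so their separate values are uncertain.

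Iron acquisition at the root surface showed the same direction, with 10 of 11 tested members lower and a median of -1.07. The iron transporter IRT1 (AT4G19690) read 7.34, 7.05 and 7.26 in wild type libraries 1 to 3 and 7.06, 5.44 and 5.94 in ntrc libraries 1 to 3, a log2 fold change of -1.07 (SE 0.41). The ferric reductase FRO2 (AT1G01580) had -1.32 (SE 0.51). Genes for the synthesis of secreted coumarins, phenolics that mobilise iron, had -1.44 for F6'H1 (AT3G13610), -2.94 for S8H (AT3G12900) and -1.63 for CYP82C4 (AT4G31940). No member passed over all genes with all 6 libraries, without a block (smallest adjusted p 0.948) or with it (0.0804), by limma with Benjamini-Hochberg. In the blocked fit without pair 1, added after the data were seen, 8 of the 11 fell, among them IRT1 (-1.46, adjusted p = 0.0328), FRO2 (-1.77, 0.0242), S8H (-4.14, 0.00297) and CYP82C4 (-2.30, 0.0174), against 0 without pair 2 (smallest 0.277) or pair 3 (0.109; limma, Benjamini-Hochberg). Fits without a pair have few residual degrees of freedom, so these calls lean strongly on variance pooled over genes. Pair 1 also had the weakest within-pair median of this list, so leaving it out favours such calls. Adjusted over the list alone, 0 passed without a block and 6 with it, and camera's Benjamini-Hochberg adjusted p was 4.74e-07 at the preset correlation, with adjusted p = 0.593 with an estimated correlation.

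ntrc library 1 stood apart from the other ntrc libraries for some of these genes. It read 5.20 for S8H and 2.66 for MYB72, against 1.19 and 1.32 for S8H in the other ntrc libraries, where MYB72 was listed at 0, and 5.39 to 5.76 and 2.89 to 3.38 in wild type. Other regulators varied widely in wild type too, as bHLH100 did with 7.66, 6.57 and 5.29 in wild type and 6.12, 3.36 and 2.82 in ntrc libraries 1 to 3. Without ntrc library 1, S8H (log2 fold change -4.26, adjusted p = 0.000312), MYB72 (-3.12, 0.00195), FRO2 (-1.90, 0.0306) and F6'H1 (-2.10, 0.0382) fell (limma, Benjamini-Hochberg). Over the other fits that leave out 1 library, their adjusted p lay at 0.572 or above. ntrc library 1 was the ntrc library nearest wild type for S8H and MYB72, so leaving it out favours these calls, which are no separate evidence. Without ntrc library 1 the number of genes that fell went from 4 to 22. The within-pair medians were -0.51, -1.26 and -1.16 for the regulators, -0.35, -1.27 and -1.32 for acquisition and 0.66, 0.91 and 0.84 for storage in pairs 1 to 3. Root markers, whose share can differ between whole seedlings, had a median of 0.12 and within-pair medians of 0.43, 0.10 and -0.15.

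Among 21 tested genes of iron transport and redistribution, 15 were lower and 6 higher, with a median of -0.29. With the block the vacuolar nicotianamine transporter ZIF1 (AT5G13740) fell by 1.03 (adjusted p = 0.0234) and the mitochondrial ferric reductase FRO3 (AT1G23020) by 0.97 (adjusted p = 0.0145; limma, Benjamini-Hochberg). Both missed the threshold in the blocked fits without pair 1 (0.109 and 0.0587) or pair 2 (0.0676 and 0.0531), by the same test. Without a block both had an adjusted p of 0.948, and OPT3 (AT4G16370), a phloem transporter, had a log2 fold change of -0.94 and passed in neither fit. Adjusted over the list alone, 0 genes passed without a block, and 4 rose and 8 fell with it. Camera's Benjamini-Hochberg adjusted p was 0.0340 at the preset correlation (adjusted p = 0.676 with an estimated correlation). It was 0.440 without wild type library 1, where the median was -0.11, and 0.410 without ntrc library 2, where it was -0.094, and 0.000467 to 0.0391 without each of the others.

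Photosynthetic antenna genes were slightly higher and flavonoid genes lower. All 20 tested light-harvesting genes had a positive fold change, with a median of 0.36 that fell to 0.12 under quantile normalization, and camera's Benjamini-Hochberg adjusted p was 1.64e-05 (adjusted p = 0.676 with an estimated correlation). Over the fits that leave out 1 library the antenna median lay between 0.16 (without wild type library 1) and 0.55 (without ntrc library 1). With the block LHCB2.3 (AT3G27690) rose by 0.66 (adjusted p = 0.0469; 0.0784 with quantile normalization and up to 0.159 without 1 pair), and adjusted over the list alone 16 genes passed, against 0 without it (limma, Benjamini-Hochberg). Near-identical LHCB1 copies make single values of that family uncertain. All 13 flavonoid genes were lower, with a median of -0.39 and -0.37 for the regulator MYB12 (AT2G47460). Camera's Benjamini-Hochberg adjusted p was 1.04e-04 (adjusted p = 0.676 with an estimated correlation), and without wild type library 1 it was 0.412 with a median of -0.093. Adjusted over the list alone, 4 flavonoid genes passed with the block and 0 without.

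Copper and zinc genes had 15 of 19 members higher, 14 under either other scaling, with a median of 0.14 and a camera Benjamini-Hochberg adjusted p of 4.53e-04 (adjusted p = 0.593 with an estimated correlation). The reductase FRO4 (AT5G23980) rose by 1.09 with the block (adjusted p = 0.0469; 0.0506 to 0.131 with another scaling or without 1 pair), and the zinc transporters ZIP3 (AT2G32270) and IRT3 (AT1G60960) had log2 fold changes of 1.02 and 0.50, with adjusted p of 0.0922 and 0.0889 with the block (limma, Benjamini-Hochberg). The copper chaperone CCH (AT3G56240) had 0.62. Adjusted over the list alone, 6 members passed with the block and 0 without. In the block fit fry also passed this list (Benjamini-Hochberg adjusted p = 0.0212), light harvesting (0.0212) and iron storage (0.0413), and none of the 22 without a block (smallest 0.591). In the blocked fit camera gave adjusted p = 0.346 for each of these 3 lists with an estimated correlation (Benjamini-Hochberg).

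The other 3 lists past camera's threshold had small medians: 0.16 for photosystem and electron transport genes (27 of 31 higher), -0.14 for starch genes (20 of 23 lower) and 0.17 for early auxin genes (8 of 9 higher). Their Benjamini-Hochberg adjusted p from camera were 0.00572, 0.00160 and 0.0152, with adjusted p = 0.884, 0.676 and 0.676 with an estimated correlation. The electron transport median was 0.0066 under quantile normalization, with 18 of 31 genes higher. That list also missed the threshold without wild type library 1 (median 0.020), wild type library 3 (0.20) or ntrc library 2 (0.066), the starch list without wild type library 1 (-0.046), and the auxin list without wild type library 2 (0.071) or ntrc library 3 (0.12). PSAN (AT5G64040), GWD1 (AT1G10760) and IAA4 (AT5G43700), the members with the smallest p, had log2 fold changes of 0.46, -0.28 and 0.28, and no member of the 3 lists passed over all genes in either fit.

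**Figure D2:**
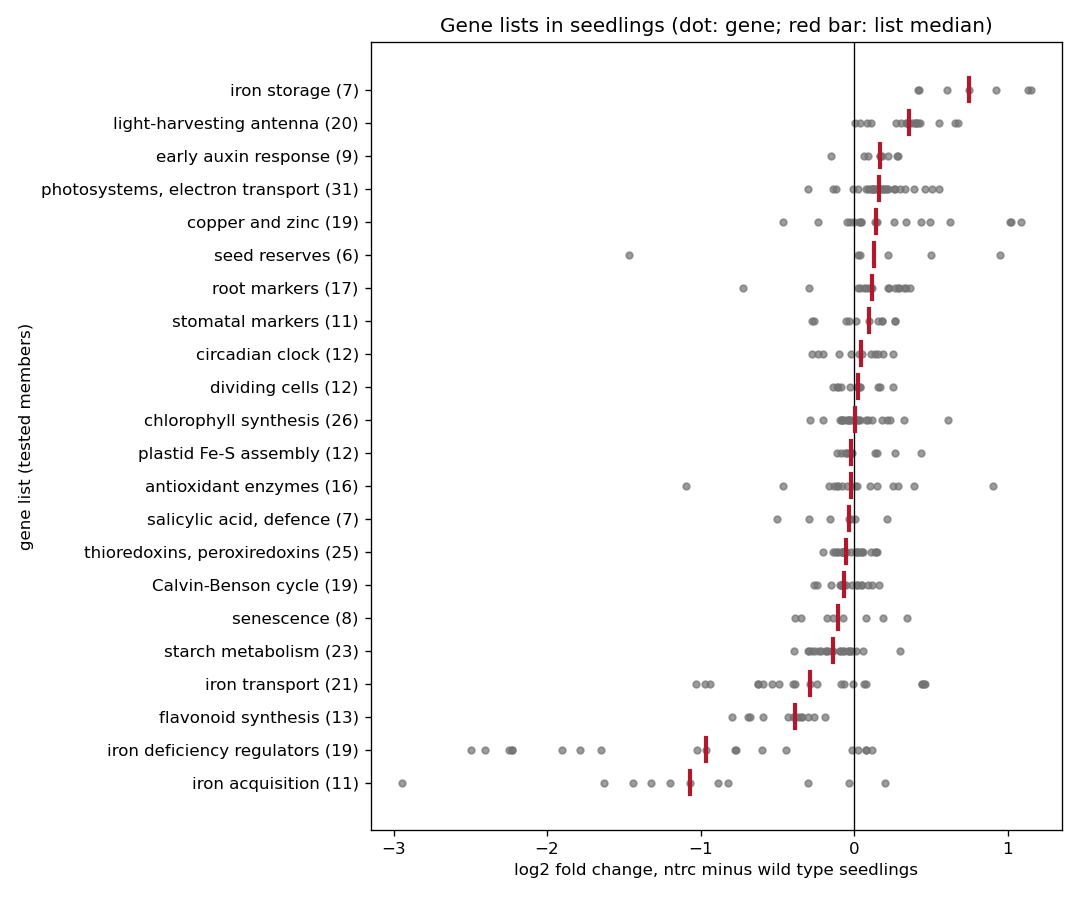
Dots are log2 fold changes of single genes, ntrc minus wild type seedlings, on the horizontal axis, by gene list with the number of tested members, and red bars are list medians. Medians ran from -1.07 for iron acquisition to 0.75 for iron storage, and the 12 lists that missed camera's threshold lay between -0.10 and 0.13.

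The other 12 lists missed the threshold. Plastid iron-sulfur assembly, which needs iron, had a median of -0.020 over 12 genes (SUFB, AT4G04770, 0.43), chlorophyll synthesis 0.0061 over 26 (HEMA1, AT1G58290, 0.61), the Calvin-Benson cycle -0.064 over 19 (TKL1, AT3G60750, -0.24) and chloroplast thioredoxins and peroxiredoxins -0.050 over 25 (PRXQ, AT3G26060, -0.20). Antioxidant enzymes had -0.022 over 16, of which the iron superoxide dismutase FSD1 (AT4G25100) rose by 0.91 with the block (adjusted p = 0.0408, limma with Benjamini-Hochberg; 0.0505 to 0.108 with another scaling or without 1 pair, and 0.948 without a block). Clock genes had 0.042 (ELF3, AT2G25930, -0.28), salicylic acid defence -0.035 (CBP60G, AT5G26920, -0.50), senescence -0.10 (ORE1, AT5G39610, -0.38) and seed reserves 0.13 (OLEO2, AT5G40420, 0.95). Root markers had 0.12 (ESB1, AT2G28670, -0.73), stomatal markers 0.096 (FAMA, AT3G24140, 0.27) and dividing-cell markers 0.024 (KNOLLE, AT1G08560, 0.26). The genes in parentheses had the smallest p of their list and none passed over all genes in either fit, while ESB1 fell in the blocked fit without pair 3 (log2 fold change -0.97, adjusted p = 0.0210; limma, Benjamini-Hochberg). Some of the 12 passed camera at the preset correlation elsewhere (Benjamini-Hochberg adjusted): the Calvin-Benson cycle under quantile normalization (median -0.16, 16 of 19 lower, adjusted p = 3.18e-04) and without wild type library 1 (-0.11, 0.0379) or 3 (-0.11, 0.0151), chlorophyll synthesis without wild type library 2 (0.11, 0.00835), thioredoxins and peroxiredoxins without wild type library 3 (-0.055, 0.0359), root markers without wild type library 3 (0.34, 6.32e-05), and seed reserves without ntrc library 1 (0.48, 0.00111) or wild type library 2 (0.43, 0.00820). With an estimated correlation these had adjusted p = 0.418 or above. The chlorophyll median was -0.014 under quantile normalization. The median and the camera direction differed in sign for 3 lists, all among these 12.

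The second axis of the design is the stage, which came with another tissue, light regime, medium, kit and scaling, so levels are set side by side without a test. In adult ntrc leaves the iron acquisition genes ranked low, at a median percentile of 37.0 ± 1.31 among nuclear genes of a library, against 85.5 ± 5.47 in ntrc and 92.4 ± 1.28 in wild type seedlings (mean ± SD, n = 3). IRT1 was listed at 0 in 2 adult libraries, and bHLH39 and S8H at 0 in all 3. Iron regulators stood at 51.2 ± 1.4, 67.3 ± 15.3 and 86.0 ± 6.18 in the same order, and root markers at 16.2 ± 3.6, 65.9 ± 0.804 and 65.6 ± 3.82. Iron storage genes stood at 43.4 ± 1.67, 63.2 ± 5.27 and 53.4 ± 3.03 in that order. FER1 ranked at 98.2 ± 0.656 in adult leaves and 98.9 ± 0.417 in ntrc seedlings, and BTS at 89.7 ± 0.613 and 87.6 ± 4.26. Salicylic acid defence genes ranked at 78.2 ± 5.09 in adult leaves and 41.2 ± 0.488 in ntrc seedlings, with PR5 (AT1G75040) at 96.8 ± 0.257 and 41.0 ± 0.197, and senescence genes at 78.4 ± 4.36 and 59.9 ± 1.18. The median members of the antenna, Calvin-Benson and electron transport lists lay above the 99th percentile at both stages.

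**Figure D3:**
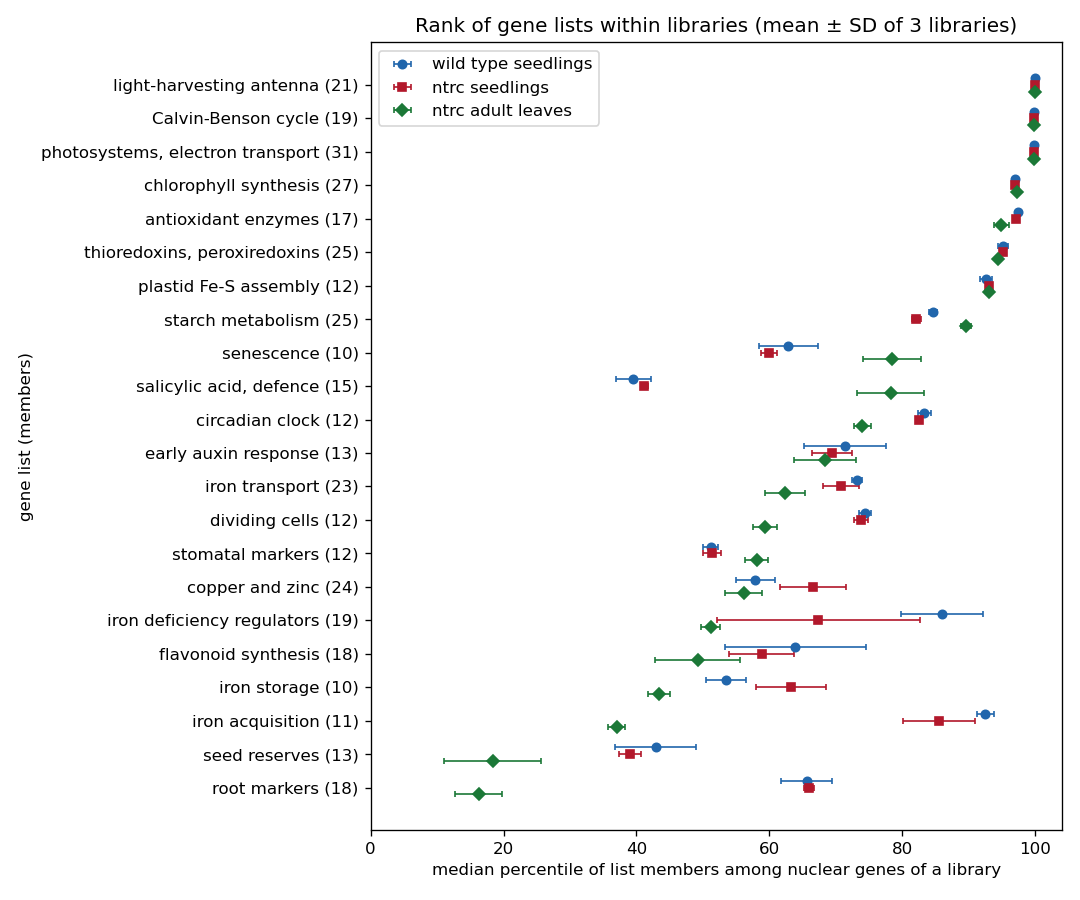
The horizontal axis is the median percentile of a list's members among the nuclear genes of a library, as mean ± SD of 3 libraries, for wild type seedlings (blue circles), ntrc seedlings (red squares) and adult ntrc leaves (green diamonds). Iron acquisition genes stood at 92.4, 85.5 and 37.0 in that order and defence genes at 39.5, 41.2 and 78.2.

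Plastid genes took 48.1 ± 1.12% of the summed FPKM in adult ntrc leaves, 0.321 ± 0.0918% in wild type seedlings and 0.431 ± 0.1% in ntrc seedlings (mean ± SD, n = 3). Mitochondrial genes took 1.4 ± 0.0817%, 0.0223 ± 0.00620% and 0.0260 ± 0.00502% in that order. Of the nuclear FPKM in adult leaves, 69.0% belonged to protein-coding genes and 10.8% to small nuclear RNAs, against 97.7% and 0.00646% in ntrc seedlings. The plastid gene ATCG00020 alone took 16.6% to 17.4% of an adult library. The kits differed between the stages in the same way as the tissue.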

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

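All tests in this part except that of the neighbouring genes were chosen after the results were seen. AT1G75945 stood out in the adult leaves, which the comparison of the genotypes does not use: its lowest adult ntrc library read 3.31 on the log2(FPKM + 1) scale, above the highest wild type seedling library at 0.42, although the 2 stages were scaled separately. Single libraries in these groups of 3 were not tested as outliers.

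The 4 genes besides NTRC that passed without a block, AT1G75945, AT4G04223, NTMC2T6.2 and ARP9, lie apart from one another and belong to none of the gene lists. A local change that also moves neighbouring genes is argued against by their nearest tested neighbours, whose median absolute log2 fold change was 0.0933. A difference carried by the ntrc line at both stages is a candidate explanation, since 4 of the 4 genes ranked closer in adult ntrc leaves to ntrc than to wild type seedlings. It stays open, because adult wild type leaves are not analysed here and leaves may differ from seedlings in these genes in any genotype. A sequence difference of the line at these loci and an effect of the lost enzyme were not tested.

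The count of 5 genes without a block compares with at most 3 in the other 9 of the 10 splits of the 6 seedling libraries, and the real split was the only 1 with as many. The 5 include NTRC, the mutated gene itself. In the other splits, differences between the genotypes add to the spread within groups, so lower counts there are partly set in advance. With the block, 73 genes compare with at most 0 in the other splits that part all 3 pairs, so that again only 1 of these 4 splits reached the count. For the gene lists at the preset correlation, 10 passed, and 4 of the 10 splits had at least as many, with at most 13 among the others. The split with 13 set wild type libraries 1 and 3 with ntrc library 1 against the rest and parts 1 pair. Among the splits that part all 3 pairs the other counts were 6, 5 and 3. These splits are too few for a share under 0.05.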

How the results depend on the processing

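Without a block 1 gene rose and 4 fell, and the counts of rises and falls were 0 and 2 with a pseudocount of 0.1, 30 and 43 with the replicate block, and 8 falls with all 9 libraries in one fit. Added after the data were seen, the replicate block gave 27 and 45 with quantile normalization, 23 and 41 with median ratio scaling, 21 and 51 without pair 1, 6 and 23 without pair 2, and 28 and 43 without pair 3. Of the 73 blocked calls, 22, 17 and 40 remained without pairs 1, 2 and 3. Leaving out 1 library gave 0 to 2 rises and 1 to 22 falls, the last without ntrc library 1. The cause of these moves was not tested, except that fewer libraries enter the fits that leave 1 out.

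Of 22 lists, 10 passed camera at the preset correlation, 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation (smallest adjusted p 0.346) and 3 with the block and fry. The medians of -1.07 for iron acquisition, -0.96 for the regulators, 0.75 for storage and -0.29 for transport do not move with the list test, and their adjusted p rose to 0.593, 0.593, 0.593 and 0.676 with an estimated correlation and to 0.591, 0.591, 0.591 and 0.907 with fry. Iron transport also missed the threshold under median ratio scaling (median -0.29, adjusted p = 0.0509), and its median lay between -0.56 and -0.094 over the fits that leave out 1 library. Over those fits the medians were -1.52 to -0.71 for acquisition, -1.34 to -0.71 for regulators and 0.58 to 0.94 for storage, all past camera's threshold at the preset correlation. With an estimated correlation none of these lists passed in any of those fits (camera, Benjamini-Hochberg adjusted p of 0.418 or above). With all libraries and no block, the estimate was 0.59 for acquisition, 0.30 for regulators, 0.77 for storage and 0.16 for transport. It was 0.71 for light harvesting and 0.77 for flavonoids. With the block these were 0.63, 0.42, 0.14, 0.18, 0.074 and 0.17 in that order. All lie above the preset of 0.01, so p-values at the preset can be too small for these lists.

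Among the results for single genes, 959 kept their direction and side, 122 gained a call, 4 of them without ntrc library 1 and the others in blocked fits (25 with all pairs and the main scaling), 15 lost one, and 1 turned: CBP60G, whose log2 fold change lay between -0.83 and 0.085 over the fits that leave out 1 library, was above 0 without wild type library 1. The cause was not tested. The block changed no call of a list at the preset correlation and no other call of a named gene. No alternative was run for adult leaves against seedlings, because that test was not run, and no paired analysis was run there either. Depth is unknown, which limits what can be said of genes near 0.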

Other observations

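With the replicate number as a block, genes outside the lists also changed. The largest rises after AT1G75945 were NEET (AT5G51720, an iron-sulfur cluster protein; log2 fold change 1.47, adjusted p = 0.00954), AT5G19890 (1.46, 0.0202), the long non-coding locus AT4G31248 (1.46, 0.0234), AT5G46960 (1.42, 0.0370), the expansin EXPA2 (1.4, 0.0294), AT1G29090 (1.33, 0.00371), the polygalacturonase PGAZAT (1.3, 0.0128), AT4G01390 (1.22, 0.0198) and AT5G20820 (1.2, 0.0353), all by limma with Benjamini-Hochberg and each higher in 3 of 3 pairs. Without a block none of these 9 passed. In blocked fits without 1 pair, added after the data were seen, NEET, AT1G29090 and PGAZAT kept their call whichever pair was left out, and the other 6 missed the threshold or were not tested without at least 1 of the pairs. Whether reads of AT4G31248 were told apart from those of overlapping genes is not given in the sources used here. NEET read 6.31 ± 0.62 in wild type and 7.78 ± 0.50 in ntrc (n = 3).

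The largest falls with the block, after NTRC, were AT1G62420 (log2 fold change -2.29, adjusted p = 0.00640), RRTF1 (AT4G34410, -2.16, 0.00640), AT4G04223, the jasmonate synthesis gene LOX2 (AT3G45140, -1.99, 0.0312), NTMC2T6.2, AT4G36700 (-1.76, 0.0337), ORA47 (AT1G74930, -1.50, 0.00371), the ethylene synthesis gene ACS6 (AT4G11280, -1.42, 0.0199) and ERF13 (AT2G44840, -1.37, 0.00987), by limma with Benjamini-Hochberg and each lower in 3 of 3 pairs. Of these, AT4G04223 and NTMC2T6.2 also passed without a block. ORA47 and AT4G04223 kept their call whichever pair was left out. Without pair 1, LOX2 (0.0649), AT4G36700 (0.0649; 0.0593 without pair 3) and ACS6 (0.0587) missed the threshold (limma, Benjamini-Hochberg), and AT1G62420, RRTF1, ERF13 and NTMC2T6.2 were not tested. RRTF1, ORA47 and ERF13 are transcription factors of the ethylene response factor family. The 7 falls that passed with the block alone were all highest in the library numbered 1 of both genotypes, as were the early-response genes described below. ORA47 read 5.77, 2.54 and 2.94 in wild type and 4.16, 1.12 and 1.48 in ntrc libraries 1 to 3, and RRTF1 6.02, 2.15 and 2.67 against 4.21 and 0.15 in ntrc libraries 1 and 3, with ntrc library 2 listed at 0.

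The tests of early-response genes below used a list written after the pattern was noticed and before the values of its members were seen, and those of the iron lists were chosen after the values were seen.

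Early-response genes, a list of 19 touch, cold and wound genes of which 16 were tested, were highest in both seedling libraries numbered 1. A handling or harvest difference shared by libraries of one number is a candidate explanation: library 1 exceeded the mean of the other 2 by a median of 1.93 in wild type (16 of 16 genes higher) and of 1.43 in ntrc (15 of 16). A genotype difference in these genes beyond the shared handling was predicted to give a median of -0.3 or lower in each pair. The within-pair medians of ntrc minus wild type were -0.85, -0.24 and -0.50, so the weakest, -0.24, missed that bound and the prediction was not met. Each median was negative, and 11 of the 16 genes were lower in ntrc in every pair, so a smaller or less even difference is not excluded. With the block 0 of the 16 genes passed limma's Benjamini-Hochberg threshold.

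For the iron lists, a smaller share of root tissue as a whole in ntrc is argued against by the root markers. Their median of 0.12 lies above the -1.07 of iron acquisition by more than their SD of 0.27, a spread over genes and not over libraries. In pair 3, 13 of the 17 root markers were lower, with a median of -0.15 against -1.32 for iron acquisition. The list joins markers of several root cell types, so a shift among these types was not tested. A growth or harvest difference that libraries of one number share equally cancels in this comparison, since each genotype has 1 library of every number, and the regulators were lower in each pair, with a median of -0.51 in the weakest. What stays open is a difference in iron supply, seed iron content or harvest between single libraries, since ntrc library 1 lay near wild type for several genes, and an effect of NTRC on iron status may be one of several sources of the pattern. None of these was tested, and no list passed with an estimated correlation.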
